A study of Mus musculus with 15 samples.

How the data were processed

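Gene expression was measured by RNA sequencing in 15 mouse libraries, 3 in each of 5 groups, and the groups were taken from the sample titles. Per the labels, 4T1 mammary carcinoma cells were sequenced from culture and after recovery from the lungs of BALB/c mice, and sorted lung epithelial cells, titled by the epithelial surface protein EpCAM, were sequenced from distal lung, from the metastatic niche, and from a niche group labelled shSox9. RNA was prepared with a spin-column kit for small samples, and reads of 75 bases were planned at 30000000 per library. Some file names call the epithelial cells alveolar type 2 (AT2) cells, whereas the labels call them lung epithelial cells, and the labels' term is used here.

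The authors made one table per library with RSEM, a program that assigns reads to transcripts and sums them per gene, against the mouse genome build GRCm38, per the submitters' processing notes. These notes also name DESeq2, and they give no versions. The aligner, the annotation release, the strand setting and any filter on reads are not given in the sources used here. The deposited expected counts are estimates that need not be whole, because reads shared by several genes are split between them. In each library 11.8% to 14.1% of genes had such values. The deposited TPM values are scaled by the authors' RSEM run for transcript length, with the same total in each library, and they entered only 1 alternative analysis. The deposited FPKM values were not used. Genes with near-identical copies, such as the Cd209 family, class II histocompatibility genes and Hspa1a with Hspa1b, depend on how the authors' counting split shared reads, and genes that overlap on opposite strands could not be told apart without a known strand setting.

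All 54838 Ensembl gene identifiers were matched to GENCODE mouse release M21, whose coordinates are on GRCm38. Of them, 54809 (99.95%) had an entry, and 219 genes shared a symbol with another gene. Coordinates are 1-based. Expected counts were rounded to whole numbers before testing. Libraries held 15907316 to 30421705 counts, so that 3 counts, the limit that a count of 0 allows, corresponded to 0.0986 to 0.189 CPM (counts scaled to library size) in a single library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries within a group were checked for being one library under 2 names. Their counts differed by a chi-square of 8.28 to 43.4 per degree of freedom, so every library was counted as its own sample. The labels give each epithelial replicate as a pool of 5 lungs. For the 4T1 groups nothing says that replicates came from separate cultures or animals, so p-values there measure the spread between these libraries, which may be technical.

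Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 6 libraries of 4T1 cells were fitted apart from the 9 epithelial libraries, which shared one estimate of the spread. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. Levels are CPM after TMM scaling, as mean ± SD over 3 libraries, unless plain CPM is named. Where a group had 0 counts of a gene in all 3 libraries, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of counts is given with its 95% counting interval.

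Gene groups were 30 lists fixed before the data were examined. They cover alveolar type 2, alveolar type 1 (AT1), transitional alveolar, club, ciliated and basal cell genes, lung progenitor and stem-associated genes, cell cycle, interferon-stimulated, antigen presentation, NF-kB and inflammatory, immediate early and dissociation, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, mesenchymal transition, epithelial junction, unfolded protein and integrated stress response, p53 target, Wnt target, Notch pathway, and TGF-beta, BMP and YAP response genes, and markers of macrophages, neutrophils, lymphocytes, endothelial cells, fibroblasts, mesothelial cells, and erythroid cells and platelets. They held 462 different genes, of which 19 stood in more than 1 list. Each list of at least 3 tested members was compared with all other genes by limma's camera (limma 3.58.1, two-sided, preset inter-gene correlation of 0.01), adjusted over the lists of a comparison, and again with a correlation estimated per list. Members passing the gene-wise test were counted over all genes tested and again adjusted over the list alone.

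The genes named were set by a rule fixed at the same time. In 3 comparisons these are the 10 largest rises and 10 largest falls with an adjusted p below 0.05, a mean of at least 5 CPM in the higher group and no overlap between replicates, leaving out unnamed gene models. From each list described, up to 4 called members with the largest change follow, and Sox9, Epcam, Sftpc, Krt8 and Mki67 are always included. Xist, Cd74, C1qa and the progenitor genes followed through the subtraction were chosen after their values were seen. Single results for 2 genes that the rule names are not reported here.

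RNA of 4T1 cells in the epithelial libraries was measured from genes with high 4T1 and low distal counts. The panel planned beforehand (at least 100 CPM in cultured 4T1 cells, at most 1 CPM in distal epithelium) held only 2 genes, Klk10 and Igf2bp1. A second panel was therefore chosen after seeing the data, with 56 genes of at least 20 CPM in both 4T1 groups and a level at least 30 times lower in distal epithelium. Its median level above distal, as a share of the level in 4T1 cells in vivo, estimated the share of 4T1 RNA. Lung RNA in the 4T1 libraries was measured from 186 genes of at least 100 CPM in distal epithelium and at most 1 CPM in cultured 4T1 cells, and from Xist, a transcript of the inactive X chromosome. Of the 186 genes 23 stood in the AT2, AT1, club or ciliated lists, 8 in the macrophage or fibroblast lists and 3 in the interferon-stimulated or antigen presentation lists, so they stand for RNA of the epithelial sort and not of epithelial cells alone. Values per library were compared between both niche groups by exact permutation and by exact sign flips within pairs of one replicate number.

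The code was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. For 4T1 cells in vivo against in vitro (13763 genes), edgeR recovered 75% of 2-fold and 88.7% of 4-fold changes, and 11.2% of its calls were false. Recovery was 57.6% and 87.6% for niche against distal (17286 genes), 59.2% and 78.1% for niche labelled shSox9 against niche (17244 genes), and 52.5% and 86.7% for niche labelled shSox9 against distal (17263 genes), with 8.39%, 6.99% and 5.52% false calls. DESeq2 1.42.0 gave 16.8%, 22.8%, 24.4% and 18.2% false calls in the same order. Camera called 1 of 28 lists in the first run and 1 of 30 in the last, on genes drawn without its preset correlation. Mixtures with 0%, 5%, 10% and 20% of 4T1 counts returned shares of 0.00277%, 4.91%, 9.72% and 19.5% from the 56 genes.

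Groups share replicate numbers in the labels. Whether these pair libraries was decided from the correlation of same-numbered libraries' deviations from their group means. Between niche and niche labelled shSox9 it was 0.217, 0.167 and 0.210 across 13550 genes, each above 0.1. The number was thus treated as pairing them, from the data and not a stated design. Genes are not independent replicates. Differently numbered libraries also passed 0.1 (0.257, replicate 1 labelled shSox9 with distal replicate 3), so the pairing is uncertain. In the other comparisons at least 1 pair fell below 0.1.

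Alternatives were DESeq2 with its own size factors, edgeR with RLE factors, no filter on low counts, limma on log2(TPM + 1), the replicate number as a block, fits of only the 6 libraries compared, and leaving out each library in turn. Added after seeing the data were a fit after subtracting the estimated 4T1 share from the niche libraries, the block with 6 libraries, list tests after this subtraction with Sox9 left out, and a fit without genes whose rise in vivo a 5% share of lung RNA could account for. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.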

Results

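Transcript levels were measured in 4T1 cells, a mammary carcinoma line from a BALB/c mouse that colonises the lung after injection into the tail vein, and in lung epithelial cells from the same kind of host. The 4T1 cells were taken from culture or from lungs 7 days after injection. The epithelial cells came from lungs 7 days after injection of 800000 4T1 cells of a kind that labels its neighbours, either from the labelled metastatic niche or from distal lung, and a further niche group carried the label shSox9. Which cells received the hairpin against Sox9 is not given in the sources used here. Each of the 5 groups had 3 libraries. In order of replicate, libraries held 21167475, 30421705 and 22998698 counts for 4T1 cells in vitro, 18854314, 19031705 and 18100745 for 4T1 cells in vivo, and 19241055, 16090224 and 15907316 for distal epithelium. They held 21581590, 21559603 and 16034105 counts for niche epithelium and 18978397, 20208920 and 18391067 for niche libraries labelled shSox9.

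Genes with at least 1 count numbered 19461 ± 326 (SD, n = 3) in 4T1 cells in vitro, 21026 ± 103 in vivo, 23417 ± 119 in distal epithelium, 23223 ± 520 in niche epithelium and 23365 ± 377 in the niche libraries labelled shSox9. Mitochondrially encoded genes took 0.733% ± 0.0688 of counts in 4T1 cells in vitro, 1.20% ± 0.0640 in vivo, 1.18% ± 0.111 in distal epithelium, 1.15% ± 0.143 in niche epithelium and 1.70% ± 0.427 in the niche libraries labelled shSox9. The 10 most abundant genes took 28.1% ± 2.19 of counts in distal epithelium, 6.99% ± 0.338 in niche epithelium and 9.75% ± 1.25 in niche libraries labelled shSox9. Sftpc, which encodes surfactant protein C of AT2 cells, alone took 16.7% to 20.5% in distal epithelium. TMM factors were accordingly lowest there, at 0.841 to 0.912.

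Sox9, a transcription factor of distal lung progenitors during development, is a protein-coding gene on chromosome 11 (GRCm38 112782224 to 112787760, ENSMUSG00000000567). In plain CPM it stood at 4.37, 5.41 and 5.59 in distal epithelium, at 64.9, 58.8 and 33.0 in niche epithelium, and at 91.1, 62.3 and 36.8 in the niche libraries labelled shSox9. The means were 5.12 ± 0.662, 52.2 ± 16.9 and 63.4 ± 27.2 CPM (SD, n = 3), against 207 ± 16.8 in 4T1 cells in vitro and 350 ± 62.9 in vivo. Sox9 was thus not lower under the label that names it. Its log2 fold change between niche libraries labelled shSox9 and niche libraries was 0.26 (SE 0.27, edgeR adjusted p = 0.55), with an adjusted p of 0.189 to 0.952 when each library was left out in turn. Within the 3 pairs of one replicate number it was higher under the label each time, and with this number as a block the log2 fold change was 0.24 (SE 0.20, edgeR adjusted p = 0.443, and SE 0.10, adjusted p = 0.149, with only the 6 libraries). The group name below repeats the label only, and no direction drawn from it is a measured effect of lower Sox9.

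The epithelial libraries of the niche also held transcripts of the 4T1 panel, read here as an estimated share of 4T1 RNA. Panel genes were chosen by low distal counts, so their expression by host cells of the niche was not excluded. Over the 56 panel genes, 4T1 transcripts came to 19.9%, 20% and 11.7% of their in vivo level in the 3 niche libraries and to 20.9%, 14.4% and 9.88% in the 3 labelled shSox9, with means of 17.2% ± 4.79 and 15.1% ± 5.55 (SD, n = 3). Distal epithelium stood at -0.0353% ± 0.432. Between both niche groups this share differed by -2.14 points (exact permutation test, two-sided, p = 0.7, where 0.1 is the smallest p that 3 against 3 libraries allow, and p = 0.5 by exact sign flips within the 3 pairs, where 0.25 is the smallest). The size of this difference depended on the panel. The 2 genes of the panel planned beforehand stood at 24.3%, 25.6% and 12.2% in the niche, at 12%, 3.81% and 5.13% under the label and at 2.19% to 2.81% in distal epithelium. This difference of -13.7 points had no overlap (exact permutation test p = 0.1, and p = 0.25 by sign flips, both the smallest possible). With 3 genes, from limits of 50 and 0.5 CPM, the values were 39.8%, 52.7% and 14.4% in the niche and 4.88% to 8.51% under the label. Conversely, 186 genes abundant in distal epithelium and nearly absent from cultured 4T1 cells summed to 1.85%, 2.61% and 4.26% of their niche level in the 3 in vivo 4T1 libraries, with medians of 0.653%, 0.716% and 1.38%, and the sum was 0.0378% ± 0.00636 in vitro. Xist had 0 counts in vitro and reached 0.635%, 1.17% and 3.50% of its niche level in vivo.

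**Figure D1:**
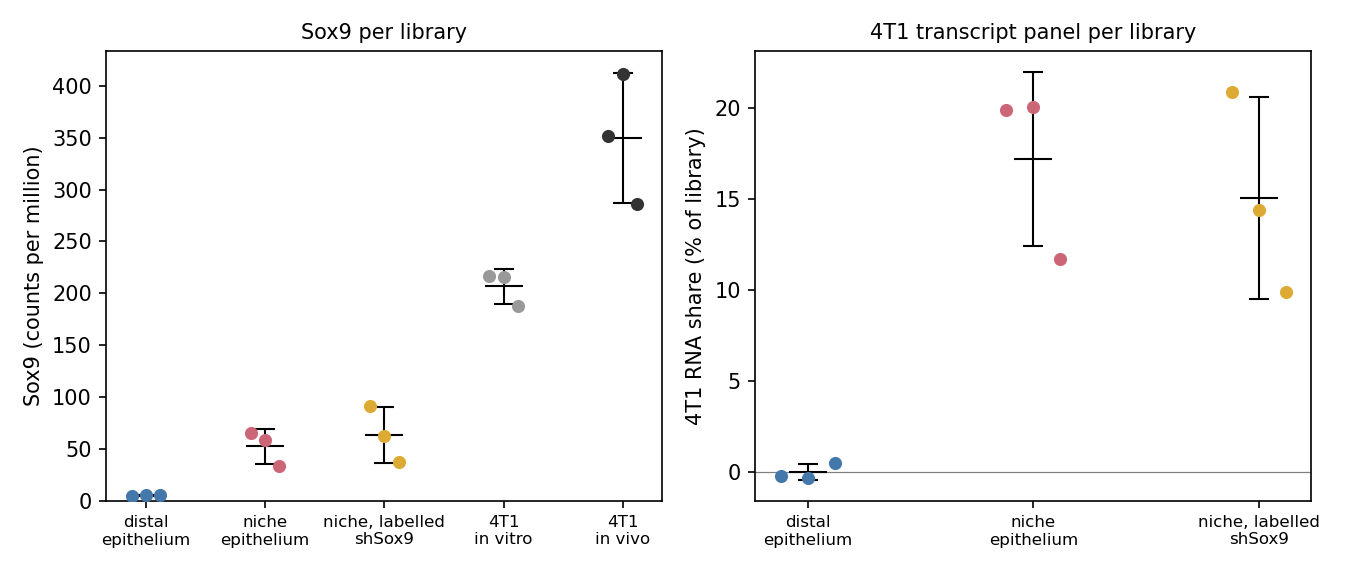
Sox9 level in plain CPM for each of the 15 libraries, and estimated share of 4T1 RNA in percent for each of the 9 epithelial libraries, with points for libraries, horizontal lines for means and error bars for SD (n = 3). Sox9 was higher in each of the 6 niche libraries (33.0 to 91.1 CPM) than in the 3 distal libraries. In these 6 the estimated share of 4T1 RNA was 9.88% to 20.9%.

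The first comparison asked how the transcriptome of 4T1 cells changed as they grew out in the lung. Interferon-stimulated, antigen presentation and immediate early genes were higher in cells recovered from lung than in culture, and genes of hypoxia and glycolysis, cholesterol synthesis and fatty acid synthesis were lower. With an estimated correlation the adjusted p of these lists was 0.22, 0.15, 0.013, 0.20, 0.20 and 0.17 in this order. The antigen presentation gene H2-Eb1, the beta chain of a class II histocompatibility molecule, was not counted in vitro and reached 82.3 ± 48.7 CPM (SD, n = 3) in vivo, at least 1960-fold higher. Ccn2, a secreted matricellular protein induced through YAP, fell by 3.82 on the log2 scale, from 89.7 ± 8.41 to 6.37 ± 0.396 CPM. Sox9 itself was 1.56-fold higher in vivo (log2 fold change 0.64, SE 0.13, edgeR adjusted p = 0.0024), with no overlap between the 3 libraries of each group. edgeR called 7151 of 14022 genes tested, 3781 higher and 3370 lower in vivo, and of these 2081 and 535 changed at least 2-fold. The 3 libraries of one group did not overlap those of the other for 60.7% of genes, where chance gives 10%.

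Among the largest rises in vivo, 7 genes had 0 counts in all 3 cultures. Besides H2-Eb1 (chromosome 17, 34305867 to 34316674, ENSMUSG00000060586, protein coding), these were Ido1 (chromosome 8, 24584136 to 24597009, ENSMUSG00000031551), an enzyme of tryptophan breakdown, at least 1421-fold higher at 59.7 ± 24.9 CPM, and the macrophage-associated chitinase-like gene Chil3, at least 1028-fold higher. Apol6 was at least 824-fold, the ubiquitin-like modifier Ubd at least 593-fold and the lysosomal membrane gene Laptm5 of leukocytes at least 338-fold higher. H19, an imprinted long noncoding RNA on chromosome 7 (142575529 to 142578143), stood at 15.5 ± 0.924 CPM in vivo, at least 368.5-fold higher. H2-Aa and Ctss had 1 count each in vitro, and their ratios were 6802 (95% counting interval 1221 to 268680) and 4661 (837 to 184110). Lyz2, the lysozyme of macrophages and AT2 cells, rose by 11.47 on the log2 scale (SE 1.36, edgeR adjusted p = 0.00014) to 216 ± 249 CPM, and ranged from 48.4 to 502 CPM among the 3 libraries. For these 10 genes the edgeR adjusted p was at most 0.0015.

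Falls were smaller in fold than the largest rises. The protease inhibitor Serpinb2 changed by -5.54 (SE 0.76), the membrane proteolipid Mal by -5.08 (0.20), S100a7a by -4.94 (0.36), the oxygenase Cyp1b1 by -4.83 (0.29) and Mfap3l by -4.83 (0.38). The ligand Wnt7a (chromosome 6, 91363981 to 91411363, ENSMUSG00000030093, protein coding) changed by -4.51 (0.19), from 35.0 ± 6.09 to 1.53 ± 0.225 CPM. Ctsw, the TEAD cofactor Vgll3, Ccn2 (chromosome 10, 24595442 to 24598683) and the fibroblast growth factor-binding gene Fgfbp1 changed by -4.31, -3.86, -3.82 and -3.68. All 10 falls had an edgeR adjusted p of at most 0.00031. Epcam changed by -0.64 (SE 0.14, edgeR adjusted p = 0.0043) and Krt8, an epithelial keratin, by 0.29 (0.11, adjusted p = 0.044). The call of Krt8 was lost when in vivo replicate 1 or 3 or any of the 3 cultures was left out (adjusted p = 0.0509 to 0.176). The proliferation gene Mki67 was not called (-0.07, SE 0.09, edgeR adjusted p = 0.53).

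All 22 interferon-stimulated genes rose in vivo, with a median log2 fold change of 3.19 (camera adjusted p = 8.8e-14, and adjusted p = 0.22 with an estimated correlation). They included the guanylate-binding protein Gbp2 at 6.69 (SE 0.39), the nucleic acid sensor Zbp1 at 6.00 (0.59), the chemokine Cxcl10 at 5.80 (0.41) and the antiviral GTPase Mx1 at 5.69 (0.61). All 14 antigen presentation genes rose as well, by a median of 4.82 (camera adjusted p = 1.6e-23, and adjusted p = 0.15 with an estimated correlation). Cd74, the class II invariant chain, went from 8.44 ± 3.20 to 1225 ± 486 CPM (log2 fold change 7.19, SE 0.38), and H2-Ab1 changed by 10.70 (0.65). Of 19 NF-kB and inflammatory genes 14 rose and 4 fell, with a median of 2.40 (camera adjusted p = 6e-09, and adjusted p = 0.15 with an estimated correlation). Lcn2 at 6.39 (0.60), the adhesion molecule Icam1 at 5.17 (0.24) and the neutrophil chemokine Cxcl2 at 5.14 (0.33) were examples. Of 16 immediate early and dissociation genes 15 rose, and 16 adjusted over the list alone. Their median was 3.60 (camera adjusted p = 5.3e-40, and adjusted p = 0.013 with an estimated correlation), with the transcription factors Fos at 7.92 (0.24) and Egr1 at 4.97 (0.25) and the mRNA decay factor Zfp36 at 4.81 (0.17). The share of mitochondrially encoded counts was also higher in vivo, at 1.14% to 1.27% against 0.672% to 0.808% (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow). So was that of ribosomal RNA genes, at 0.318% ± 0.0707 against 0.199% ± 0.0418 (exact permutation test, p = 0.1). The mitochondrial ones among them took 0.234% ± 0.0293 against 0.134% ± 0.0369 (p = 0.1 by the same exact test), and the nuclear ones 0.0837% ± 0.0425 against 0.0653% ± 0.00707 (p = 0.7). Counts adjusted over the list alone were the same as those over all genes wherever only 1 count is given, here and in the paragraphs that follow. For the genes named the edgeR adjusted p was at most 7.5e-05.

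Of 20 hypoxia and glycolysis genes 16 fell (17 adjusted over the list alone), with a median of -1.17 (camera adjusted p = 7e-15, and adjusted p = 0.20 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, changed by -2.71 (SE 0.13) and the mitophagy receptor Bnip3 by -2.64 (0.13). All 18 cholesterol synthesis genes fell, by a median of -1.01 (camera adjusted p = 1.5e-12, and adjusted p = 0.20 with an estimated correlation), among them lanosterol synthase, Lss, by -1.77 (0.16). Of 15 fatty acid synthesis genes 14 fell, with a median of -0.79 (camera adjusted p = 7.6e-10, and adjusted p = 0.17 with an estimated correlation). The desaturases Scd2 and Scd1 changed by -2.87 (0.13) and -2.38 (0.13), and fatty acid synthase, Fasn, by -1.32 (0.12). Of 24 cell cycle genes 14 fell (15 adjusted over the list alone) and 2 rose, with a median of -0.30 (camera adjusted p = 0.0045, and adjusted p = 0.22 with an estimated correlation), including the mitotic kinases Aurka at -0.81 (0.08) and Plk1 at -0.63 (0.10). Each of these genes had an edgeR adjusted p of at most 0.00095.

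Of 16 mesenchymal transition genes 11 rose (14 adjusted over the list alone) and 1 fell, with a median of 0.71 (camera adjusted p = 0.0022, and adjusted p = 0.15 with an estimated correlation). The transcriptional repressor Zeb1 changed by 4.73 (SE 0.39) to 5.03 ± 1.41 CPM and the matrix gene Tgfbi by 3.64 (0.27). Of 18 epithelial junction genes 11 fell and 1 rose, with a median of -0.70 (camera adjusted p = 1.7e-06, and adjusted p = 0.15 with an estimated correlation). Ovol1 at -3.17 (0.26), the splicing regulator Esrp2 at -2.46 (0.12), Krt19 at -1.83 (0.14) and the claudin Cldn3 at -1.57 (0.15) were among them. Of 16 lung progenitor and stem-associated genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation). The surface protein Ly6a (Sca-1) changed by 7.07 (0.40), the transcription factor Klf4 by 2.11 (0.23), the laminin receptor subunit Itgb4 by 1.74 (0.11) and Id2 by 1.01 (0.21). Of 16 TGF-beta, BMP and YAP response genes 9 fell and 4 rose, with a median of -0.45 (camera adjusted p = 0.0024, and adjusted p = 0.27 with an estimated correlation). Ccn2 and Ajuba (-1.52, SE 0.10), both induced by YAP, fell, whereas Tgfbi and the BMP target Id3 (1.59, SE 0.19) rose. Across the genes named the edgeR adjusted p was at most 0.0035.

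Markers of other lung cells moved with these groups. Rises were found for 12 of 15 AT2 genes, 4 of 5 club cell genes, 11 of 13 macrophage genes, 9 of 9 fibroblast genes, 7 of 9 endothelial genes (1 fell), 6 of 7 lymphocyte genes (1 fell) and 3 of 3 neutrophil genes. The camera adjusted p values were 2.8e-08, 0.0033, 7.6e-06, 2.4e-05, 6.3e-05, 0.0096 and 0.021 in this order, and with an estimated correlation the adjusted p was 0.19, 0.17, 0.34, 0.17, 0.20, 0.34 and 0.22. Their medians, with members absent from culture set at their lower bound, were 4.93, 5.16, 6.34, 4.42, 4.74, 5.66 and 2.61, and with fitted values 4.98, 6.61, 8.68, 4.42, 5.45, 6.30 and 2.61. Levels were low, with medians in vivo of 3.24 CPM for the AT2, 5.73 for the macrophage and 2.89 for the fibroblast genes that rose. At least 1 CPM in culture was found for 5 of the 21 AT2, 2 of the 14 macrophage, 1 of the 13 lymphocyte, 1 of the 12 endothelial and 1 of the 12 fibroblast genes on the lists. Sftpc went from 1.96 ± 1.02 to 61.5 ± 22.0 CPM and the leukocyte gene Ptprc from 0.0962 ± 0.044 to 8.17 ± 7.54. Epithelial RNA at 5% of a library could account for the rise of 292 called genes, and without the 548 genes in this position edgeR called 6855 (3487 higher and 3368 lower).

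No shift was called for 10 further lists. Members rose and fell in numbers of 2 and 4 of 11 for AT1 genes (camera adjusted p = 0.39), 5 and 6 of 19 for transitional alveolar genes (0.33), 2 and 0 of 3 for ciliated cell genes (0.39), 5 and 2 of 9 for basal cell genes (0.16) and 2 and 8 of 20 for oxidative phosphorylation genes (0.18; 2 and 9 adjusted over the list alone). The numbers were 3 and 5 of 16 for unfolded protein and integrated stress response genes (camera adjusted p = 0.30), 5 and 7 of 13 for p53 target genes (0.79), 4 and 0 of 7 for Wnt target genes (0.15), 2 and 2 of 8 for Notch pathway genes (0.98) and 2 and 1 of 3 for erythroid and platelet genes (0.70). The p53 targets that rose included the antiproliferative gene Btg2 at 4.11 (SE 0.24), also an immediate early gene. Among Wnt targets the secreted inhibitor Notum rose by 2.65 (0.21). The median and mean of a list differed in sign for AT1 (-0.06 and 0.70), transitional (0.05 and -0.13), unfolded protein (0.01 and -0.08), p53 (-0.31 and 0.86) and Notch genes (0.16 and -0.07). Of the mesothelial genes 1, Msln, could be tested, too few for a test, and it fell by 1.20. Nothing about the spread between mice can be read from the 4T1 replicates, whose origin is not labelled.

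**Figure D2:**
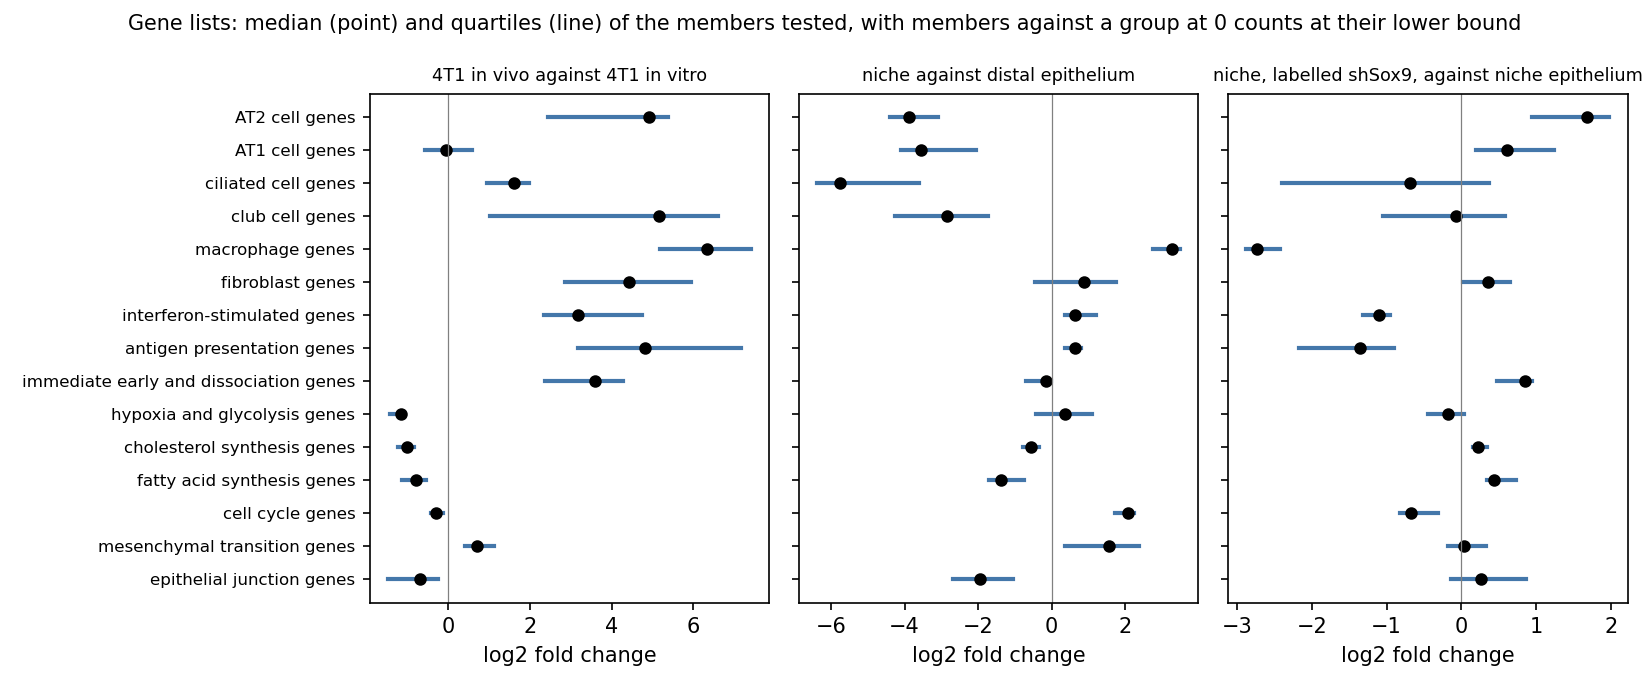
Median (points) and quartiles (lines) of the log2 fold changes of 15 of the 30 gene lists in 3 comparisons, each panel on its own axis, with members against a group at 0 counts set at their lower bound. Interferon-stimulated genes lay at a median of 3.19 in 4T1 cells in vivo and at -1.10 in niche libraries labelled shSox9 against niche epithelium, and AT2 genes at -3.88 in niche against distal epithelium.

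The second comparison set epithelial cells of the metastatic niche against those of distal lung. AT2, AT1, ciliated and club cell genes were lower in the niche, and mesenchymal transition, cell cycle, inflammatory and macrophage genes were higher. With an estimated correlation the adjusted p was 0.037, 0.028, 0.030 and 0.23, then 0.028, 0.36, 0.36 and 0.36, so 4 calls were lost. RNA of fibroblasts in the sort was not excluded as a source of the mesenchymal rise. Sftpc (chromosome 14, 70520949 to 70524081, ENSMUSG00000022097, protein coding) stood at 8930.3 ± 984 CPM in the niche and 210460 ± 30321 in distal lung (SD, n = 3), a log2 fold change of -4.56 (SE 0.32, edgeR adjusted p = 7.6e-07). Sox9 was 8.44-fold higher in the niche (log2 fold change 3.08, SE 0.32, edgeR adjusted p = 1.3e-05), in libraries with an estimated 11.7% to 20% of 4T1 RNA. The proliferation gene Mki67 rose by 1.71 (0.24, adjusted p = 0.00011). edgeR called 9579 of 17640 genes, 5025 higher and 4554 lower, and of these 2212 and 2885 changed at least 2-fold. Groups did not overlap for 64.3% of genes, where chance gives 10%. With limma on log2(TPM + 1), which changes the unit, the scaling and the test together, 9212 genes were called higher and 2397 lower, and the median of all genes moved by 0.45. Changes below are relative to TMM scaling.

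Several of the largest rises were receptors of macrophages. Cd163, the haemoglobin scavenger receptor (chromosome 6, 124304656 to 124330527, ENSMUSG00000008845, protein coding), changed by 5.66 (SE 0.43), from 0.521 ± 0.390 to 27.2 ± 6.25 CPM. The lectin receptor Cd209f changed by 7.04 (0.69), the folate receptor Folr2 by 5.09 (0.54) and Chil3 by 5.21 (0.86), the last at 474 ± 536 CPM. Cd209g had 3 counts over the distal libraries, and its ratio was 237 (95% counting interval 80.9 to 1147). Gpa33, also in the 4T1 panel, changed by 4.96 (0.51), the Wnt antagonist Dkk2 by 4.84 (0.55), Lncenc1 by 5.91 (0.91), Atg9b by 5.02 (0.61) and Kcnj10 by 5.00 (0.56). Genes of motile cilia were among the largest falls. The outer dynein arm heavy chain Dnah5 (chromosome 15, 28203752 to 28472052, ENSMUSG00000022262, protein coding) had 0 counts in the niche against 11.9 ± 2.42 CPM in distal lung, at least 251-fold lower, and Kndc1 was at least 113-fold lower. Ratios of distal to niche counts were 507 (91.0 to 20028) for Spag16, 382 (68.5 to 15080) for Drc7, 240 (66.6 to 1986) for Lrriq1, 202 (56.0 to 1669) for Spata18, 190 (65.0 to 920) for Lrrc74b and 171 (47.3 to 1411) for Cfap57, on 1 to 3 niche counts each. Fam216b and Drc1 changed by -7.15 (0.57) and -6.95 (0.70). Over all 20 genes the edgeR adjusted p was at most 0.00037.

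All 21 AT2 genes fell, with a median of -3.88 (camera adjusted p = 1.8e-41, and adjusted p = 0.037 with an estimated correlation). Besides Sftpc these were led by Sftpa1 at -4.69 (SE 0.23), the phosphate transporter Slc34a2 at -4.50 (0.24) and the chemokine Cxcl15 at -4.49 (0.20). Of 17 AT1 genes 16 fell, with a median of -3.55 (camera adjusted p = 6.8e-26, and adjusted p = 0.028 with an estimated correlation), including Igfbp2 at -5.32 (0.41), the basement membrane collagen Col4a3 at -4.58 (0.35) and the receptor Ager at -4.15 (0.21). All 13 ciliated cell genes fell, by a median of -5.76 (camera adjusted p = 6e-17, and adjusted p = 0.030 with an estimated correlation), among them Ccdc153 at -6.93 (0.44), Fam183b at -6.47 (0.39) and Tmem212 at -6.38 (0.39). Of 14 club cell genes 12 fell, with a median of -2.84 (camera adjusted p = 1.4e-05, and adjusted p = 0.23 with an estimated correlation), including the detoxifying enzymes Cbr2 at -4.74 (0.21) and Cyp2f2 at -4.63 (0.32). Epithelial junction genes fell too, 15 of 18 against 2 that rose (15 and 3 adjusted over the list alone), with a median of -1.96 (camera adjusted p = 4.7e-07, and adjusted p = 0.36 with an estimated correlation). Cldn3 changed by -3.86 (0.20) and Cldn7 by -3.18 (0.19), while Cldn4 changed by 2.99 (0.41). Epcam changed by -0.82 (0.26, edgeR adjusted p = 0.02), a call lost without distal replicate 1 (0.0595) or 3 (0.0566), after subtraction of the 4T1 share (0.12) and in limma on log2(TPM + 1) (0.34). Krt8 changed by 0.64 (0.27, edgeR adjusted p = 0.069), and was called without niche replicate 3 (0.00264), without a filter on low counts (0.00139), by DESeq2 (0.0478) and by limma on log2(TPM + 1) (0.0066).

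All 24 cell cycle genes rose, by a median of 2.08 (camera adjusted p = 1.7e-15, and adjusted p = 0.36 with an estimated correlation), including the mitotic kinesin Kif20a at 2.82 (SE 0.19) and Ccnb2 at 2.76 (0.19). After the 4T1 share was subtracted, edgeR called 11 of the 24 higher with a median of 1.10. Of 20 mesenchymal transition genes 15 rose and 2 fell, with a median of 1.57 (camera adjusted p = 8e-11, and adjusted p = 0.028 with an estimated correlation). The matrix glycoprotein Tnc changed by 3.89 (0.12), from 47.7 ± 5.71 to 707 ± 8.01 CPM, and Col5a1 by 2.54 (0.15). Of 12 fibroblast genes 7 rose and 3 fell (7 and 4 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.026, and adjusted p = 0.51 with an estimated correlation). Col1a1 at 2.35 (0.20) and Pdgfrb at 2.10 (0.14) rose, and Inmt at -1.74 (0.23) fell. The call of this list was lost without niche replicate 3 (adjusted p = 0.067) or distal replicate 1 (0.063). Of 16 TGF-beta, BMP and YAP response genes 9 rose (10 adjusted over the list alone) and 2 fell, with a median of 0.63 (camera adjusted p = 0.025, and adjusted p = 0.36 with an estimated correlation), including the receptor kinase Axl at 2.50 (0.13).

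All 14 macrophage genes rose, by a median of 3.27 (camera adjusted p = 1.6e-05, and adjusted p = 0.36 with an estimated correlation). The mannose receptor Mrc1 changed by 3.83 (SE 0.48) and the complement gene C1qb by 3.50 (0.57), from 67.5 ± 21.9 to 766 ± 146 CPM. Distal epithelium itself held at least 1 CPM of 13 of these 14 genes. Of 20 NF-kB and inflammatory genes 14 rose and 3 fell, with a median of 1.08 (camera adjusted p = 0.0018, and adjusted p = 0.36 with an estimated correlation), including the monocyte chemokine Ccl2 at 3.14 (0.18) and the acute phase gene Saa3 at 2.50 (0.23). Of 22 interferon-stimulated genes 15 rose, with a median of 0.64 (camera adjusted p = 0.00013, and adjusted p = 0.52 with an estimated correlation), including Cxcl10 at 3.10 (0.22) and Oas1a at 1.59 (0.11). Of 14 antigen presentation genes 9 rose, also with a median of 0.64 (camera adjusted p = 0.033, and adjusted p = 0.65 with an estimated correlation), including Nlrc5 at 0.96 (0.19) and the peptide transporter Tap1 at 0.86 (0.13). This call was lost without niche replicate 3 (adjusted p = 0.067) or distal replicate 2 (0.065).

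Of 16 fatty acid synthesis genes 13 fell and 1 rose, with a median of -1.39 (camera adjusted p = 2.2e-08, and adjusted p = 0.18 with an estimated correlation), including Scd1 at -3.40 (SE 0.29) and Fasn at -2.25 (0.16). Of 18 cholesterol synthesis genes 14 fell (15 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 0.0027, and adjusted p = 0.51 with an estimated correlation), including Lss at -1.55 (0.18). Of 20 oxidative phosphorylation genes 9 rose and 1 fell, with a median of 0.24 (camera adjusted p = 0.044, and adjusted p = 0.65 with an estimated correlation), including Cox5a at 0.79 (0.11) and Sdhb at 0.70 (0.09). The last call was lost after subtraction of the 4T1 share (adjusted p = 0.141), without niche replicate 1 (0.074) and without distal replicate 2 (0.095).

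Lung progenitor and stem-associated genes moved both ways. Of 24 members 12 rose and 8 fell (12 and 9 adjusted over the list alone), the median was 0.64, and the list was not called (camera adjusted p = 0.64). Sox9, the chromatin protein Hmga2 (3.74, SE 0.41) and the transcription factor Etv4 (3.44, 0.24) rose, the last 2 being genes of the 4T1 panel, and Foxp2 fell by 3.11 (0.23). Sox2, a factor of proximal airway, had 1 count over the niche libraries against 1.27 ± 0.398 CPM in distal lung, a ratio of 80.2 (95% counting interval 14.4 to 3169). After subtraction of the 4T1 share 0 Sox9 counts remained in the 3 niche libraries, and Hmga2 was no longer called (-1.87, SE 0.91, edgeR adjusted p = 0.111). Transitional alveolar genes rose in 10 and fell in 5 of 21 cases (11 and 6 adjusted over the list alone, camera adjusted p = 0.18), with the claudin Cldn4 and the urokinase receptor Plaur at 2.50 (0.20) up and the integrin subunit Itgb6 at -2.57 (0.19) down. Basal cell genes rose in 3 and fell in 4 of 11 cases (4 and 4 adjusted over the list alone, camera adjusted p = 0.73), with Krt14 at 4.06 (0.53) and Itgb4 at 2.72 (0.34).

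Further lists were not called between niche and distal epithelium. Members rose and fell in numbers of 11 and 6 of 20 for hypoxia and glycolysis genes (camera adjusted p = 0.11), 9 and 4 of 16 for unfolded protein and integrated stress response genes (0.19), 7 and 3 of 14 for p53 target genes (0.39) and 1 and 6 of 16 for immediate early and dissociation genes (0.47). The numbers were 4 and 6 of 12 for Wnt target genes (camera adjusted p = 0.16), a list that holds Sox9. After subtraction of the 4T1 share this list was called lower (adjusted p = 0.039, and adjusted p = 0.18 with an estimated correlation), but not once Sox9 was left out of it (0.096). They were 3 and 1 of 12 for Notch pathway genes (0.71), 3 and 7 of 13 for lymphocyte genes (0.24; 3 and 9 adjusted over the list alone), 2 and 1 of 9 for neutrophil genes (0.83; 2 and 0 adjusted over the list alone), 1 and 0 of 12 for endothelial genes (0.46), 0 and 3 of 6 for mesothelial genes (0.50; 1 and 3 adjusted over the list alone) and 1 and 0 of 5 for erythroid and platelet genes (0.50). The test pointed upward against a negative median and mean for basal (-0.03 and -0.24) and neutrophil genes (-0.71 and -0.04). The glycolytic enzyme Eno1 rose by 1.87 (SE 0.19), the B cell gene Cd79b fell by 2.40 (0.28), the mesothelial gene Upk3b fell by 2.41 (0.50), and the platelet chemokine Pf4, which macrophages can also express, rose by 2.22 (0.40).

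**Figure D3:**
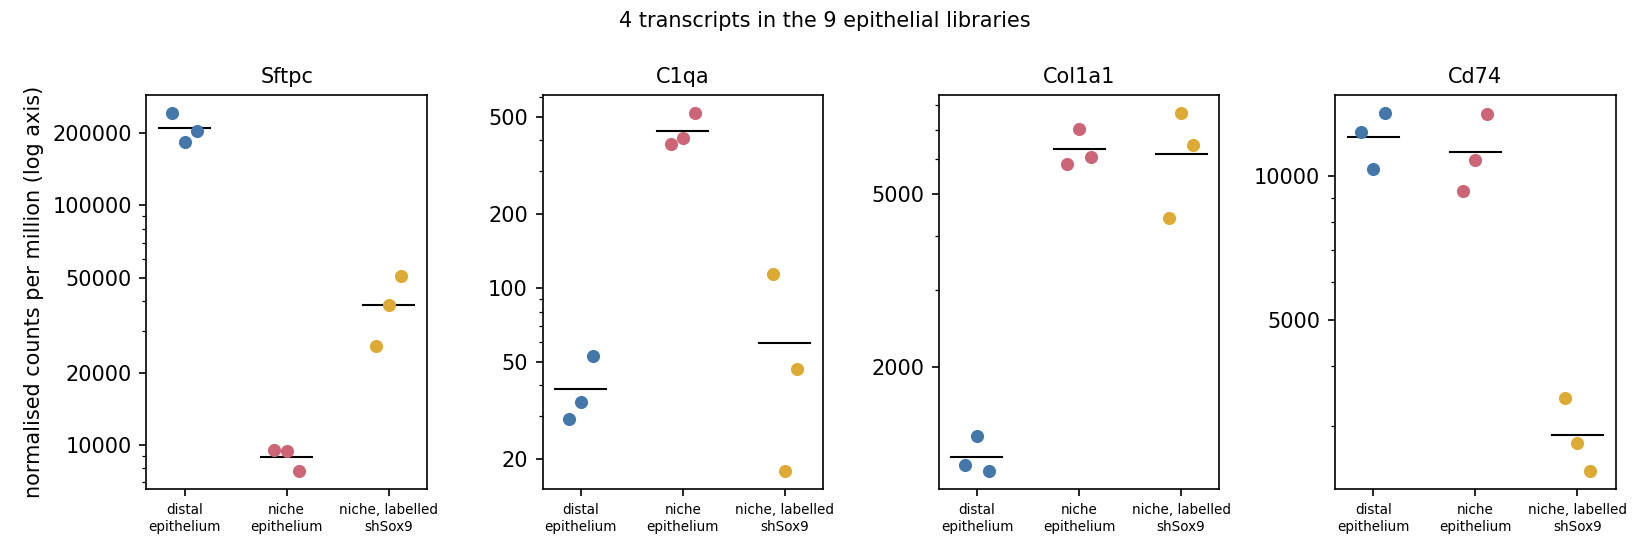
Levels of Sftpc, C1qa, Col1a1 and Cd74 (CPM after TMM scaling, log axes that differ between panels) in the 9 epithelial libraries, with points for libraries and lines for group means. Sftpc stood at 210460 ± 30321 CPM in distal, 8930.3 ± 984 in niche and 38439 ± 12578 in niche libraries labelled shSox9 (SD, n = 3).

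The third comparison set niche libraries labelled shSox9 against those without that label. AT2 genes were higher and macrophage, interferon-stimulated and antigen presentation genes lower under the label. With an estimated correlation none of these lists was called (adjusted p = 0.14, 0.14, 0.18 and 0.14 in this order). Sftpc rose to 38439 ± 12578 CPM (SD, n = 3), a log2 fold change of 2.11 (SE 0.28, edgeR adjusted p = 0.00056). The class II gene H2-Eb1 changed by -2.67 (0.27, adjusted p = 0.00015), from 767 ± 132 to 120 ± 49.9 CPM. As Sox9 was not lower, these directions belong to the label, and another cell mix in the sort was not excluded. edgeR called 3616 of 17640 genes, 1707 higher and 1909 lower, and of these 674 and 908 changed at least 2-fold. Groups did not overlap for 37.9% of genes, where chance gives 10%. Without niche replicate 1 it called 2238 genes, 940 higher and 1298 lower.

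Lectin receptors of macrophages were among the largest falls. Cd209f (chromosome 8, 4102787 to 4105835, ENSMUSG00000051906, protein coding) changed by -7.17 (SE 0.67), from 12.6 ± 0.941 to 0.0777 ± 0.135 CPM, and Cd209g, Cd209b and Chil3 by -6.84 (0.66), -4.75 (0.56) and -5.30 (0.86). The nuclease Dnase1l3 changed by -4.84 (0.50), Lncenc1 by -4.65, Gpr31b by -4.60, Kcnj10 by -4.49, the airway secretory gene Bpifa1 by -4.43 and the eosinophil-associated ribonuclease Ear2 by -4.08. Most of the largest rises were in genes of low level. Ttc21a changed by 3.51 (0.40), to 6.44 ± 1.44 CPM, the dopamine-regulated phosphoprotein Ppp1r1b by 2.69 (0.34), the transcription factor Tfcp2l1 by 2.62 (0.39) and the transporter Abca17 (chromosome 17, 24264259 to 24351068) by 2.59 (0.25). Tex15, Syt7, the AT2 gene S100g, Bend7 and Myh7 changed by 2.50, 2.50, 2.48, 2.44 and 2.42. The bone sialoprotein gene Ibsp changed by 2.94 (0.72), a call lost without replicate 1 labelled shSox9 (edgeR adjusted p = 0.0522) or niche replicate 2 (0.0597). For these 20 genes the edgeR adjusted p was at most 0.014.

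Of 21 AT2 genes 18 rose, with a median of 1.68 (camera adjusted p = 1.6e-27, and adjusted p = 0.14 with an estimated correlation). Complement component Hc at 2.27 (SE 0.22) and Slc34a2 at 2.11 (0.21) were among them. Of 17 AT1 genes 9 rose, with a median of 0.61 (camera adjusted p = 2.3e-06, and adjusted p = 0.19 with an estimated correlation), including the alveolar claudin Cldn18 at 1.95 (0.18) and Ager at 1.49 (0.19). Fatty acid synthesis genes rose in 10 of 16 cases (11 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 2.3e-06, and adjusted p = 0.19 with an estimated correlation), including Scd1 at 1.85 (0.28) and Fasn at 1.15 (0.16). Immediate early and dissociation genes rose in 11 of 16 cases (12 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 2e-07, and adjusted p = 0.36 with an estimated correlation), including Nr4a1 at 1.39 (0.21) and Egr1 at 1.08 (0.18). The share of mitochondrially encoded counts was higher under the label in each of the 3 pairs of one number, by a mean of 0.546 percentage points (exact sign flips, two-sided, p = 0.25, the smallest possible; exact permutation test without pairs, p = 0.3). Ribosomal RNA genes took 0.452% ± 0.0913 under the label and 0.367% ± 0.0383 in the niche, likewise higher in each of the 3 pairs (p = 0.25 and 0.3 by the same exact tests). The mitochondrial ones took 0.360% ± 0.0838 and 0.275% ± 0.0458, higher in 3 pairs, and the nuclear ones 0.0919% ± 0.00780 and 0.0916% ± 0.00895, higher in 1 pair. Of 12 Wnt target genes 5 rose, with a median of 0.43 (camera adjusted p = 0.0037, and adjusted p = 0.14 with an estimated correlation), including the feedback inhibitors Nkd1 at 1.22 (0.12) and Notum at 0.97 (0.17). Every gene named had an edgeR adjusted p of at most 0.0027.

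All 14 macrophage genes but 1 fell, with a median of -2.74 (camera adjusted p = 1.8e-16, and adjusted p = 0.14 with an estimated correlation). The cathepsin Ctss changed by -2.98 (SE 0.51) and C1qa by -2.87 (0.51), from 437 ± 70.9 to 59.6 ± 49.4 CPM, against 38.8 ± 12.5 in distal lung. Of 22 interferon-stimulated genes 21 fell, with a median of -1.10 (camera adjusted p = 6.5e-24, and adjusted p = 0.18 with an estimated correlation), including Ifi44 at -2.04 (0.17), Oas1a at -1.92 (0.11) and the interferon regulatory factor Irf7 at -1.56 (0.16). All 14 antigen presentation genes fell, by a median of -1.36 (camera adjusted p = 6.1e-30, and adjusted p = 0.14 with an estimated correlation), including H2-Ab1 at -2.40 (0.22) and H2-DMa at -2.24 (0.17). Cell cycle genes fell in 13 of 24 cases (15 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 3.6e-06, and adjusted p = 0.64 with an estimated correlation), including the kinases Aurkb at -1.35 (0.27) and Cdk1 at -1.07 (0.23). Mki67 was not called (-0.31, SE 0.23, edgeR adjusted p = 0.37). Among the called genes named the edgeR adjusted p was at most 0.0074.

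Smaller shifts were called for 4 lists. Cholesterol synthesis genes rose in 4 of 18 cases (median 0.22, camera adjusted p = 0.039, and adjusted p = 0.67 with an estimated correlation) and epithelial junction genes rose in 6 and fell in 1 of 18 cases (8 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.033, and adjusted p = 0.68 with an estimated correlation), with Cldn3 at 1.65 (SE 0.19). Oxidative phosphorylation genes fell in 4 of 20 cases (median -0.18, camera adjusted p = 0.032, and adjusted p = 0.64 with an estimated correlation), with Cox5a at -0.59 (0.11). Lymphocyte genes fell in 3 and rose in 1 of 13 cases (median -0.44, camera adjusted p = 0.033, and adjusted p = 0.64 with an estimated correlation), with Cd52 at -2.69 (0.37), Ptprc at -2.12 (0.30) and Cd3e at 1.28 (0.31). Each call rested on single libraries: cholesterol synthesis was lost without replicate 1 or 2 labelled shSox9 or niche replicate 2 (adjusted p = 0.085, 0.069 and 0.104), junction without replicate 1 labelled shSox9 or niche replicate 3 (0.099 and 0.796), oxidative phosphorylation without replicate 1 of either group (0.153 labelled shSox9 and 0.078 niche) and with the replicate number as a block in the 6 libraries (0.066) and lymphocyte without niche replicate 1 (0.078). Epcam changed by -1.0 (SE 0.26, edgeR adjusted p = 0.021), a call lost without replicate 2 or 3 labelled shSox9 or niche replicate 1 or 2, by limma on log2(TPM + 1) and from only the 6 libraries (0.052 to 0.0905), and Krt8 by 0.08 (0.27, adjusted p = 0.86).

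No shift was called for the remaining lists. Members rose and fell in numbers of 6 and 3 of 24 for progenitor and stem-associated genes (7 and 3 adjusted over the list alone, camera adjusted p = 0.072), 0 and 4 of 13 for ciliated cell genes (1 and 5 adjusted over the list alone, 0.070), 4 and 0 of 12 for fibroblast genes (5 and 0 adjusted over the list alone, 0.062), 1 and 3 of 21 for transitional alveolar genes (2 and 5 adjusted over the list alone, 0.33), 2 and 1 of 14 for club cell genes (0.87) and 1 and 3 of 11 for basal cell genes (0.87). With the replicate number as a block camera called ciliated (adjusted p = 0.043, and adjusted p = 0.28 with an estimated correlation) and fibroblast genes (adjusted p = 0.030, and adjusted p = 0.355 with an estimated correlation). After subtraction of the 4T1 share it called progenitor genes (13 rose and 3 fell, adjusted p = 0.0017, and adjusted p = 0.14 with an estimated correlation), and with Sox9 left out of the list the adjusted p was 0.0078, and adjusted p = 0.14 with an estimated correlation. Without single libraries it called progenitor genes (replicate 2 or 3 labelled shSox9 or niche replicate 2, lowest adjusted p = 0.012), ciliated genes (replicate 2 labelled shSox9 or niche replicate 1 or 3, 0.019), fibroblast genes (replicate 1 labelled shSox9 or niche replicate 3, 0.010), endothelial genes (replicate 3 of either group, 0.0027), mesothelial genes (replicate 2 labelled shSox9 or niche replicate 3, 0.0096) and transitional genes (niche replicate 3, 0.018). None of these lists was called in the same fits with an estimated correlation (adjusted p = 0.33 to 0.64). Of the progenitor list Foxp2 rose by 1.76 (SE 0.23) and Ly6a fell by 1.59 (0.21), and of the ciliated list the regulator Foxj1 fell by 3.94 (0.38). The basal median was -0.02, and 0.62 with the member at 0 counts set at its bound. The numbers were 4 and 4 of 20 for NF-kB and inflammatory genes (camera adjusted p = 0.72), 1 and 4 of 20 for hypoxia and glycolysis genes (1 and 7 adjusted over the list alone, 0.22), 2 and 4 of 20 for mesenchymal transition genes (0.87), 1 and 2 of 16 for unfolded protein and integrated stress response genes (2 and 4 adjusted over the list alone, 0.42), 2 and 2 of 14 for p53 target genes (0.87), 1 and 0 of 12 for Notch pathway genes (0 and 0 adjusted over the list alone, 0.87), and 3 and 3 of 16 for TGF-beta, BMP and YAP response genes (6 and 3 adjusted over the list alone, 0.98). They were 0 and 0 of 9 for neutrophil genes (0.72), 0 and 2 of 12 for endothelial genes (0 and 0 adjusted over the list alone, 0.13), 0 and 0 of 6 for mesothelial genes (0.25) and 0 and 1 of 5 for erythroid and platelet genes (0.27). Median and mean differed in sign for mesenchymal (0.04 and -0.04), Notch (-0.11 and 0.03) and TGF-beta, BMP and YAP response genes (0.05 and -0.11), and the test pointed upward against both for inflammatory genes (-0.12 and -0.21). Within the inflammatory list Tnf fell by 2.65 (SE 0.45) and the neutrophil chemokine Cxcl1 rose by 1.5 (0.12).

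The niche libraries labelled shSox9 also differed from distal epithelium. Sox9 was 10.1-fold higher (log2 fold change 3.34, SE 0.32, edgeR adjusted p = 1.2e-05), Sftpc changed by -2.45 (0.29, adjusted p = 5.1e-05), Epcam by -1.81 (0.27, adjusted p = 0.00026), Mki67 by 1.40 (0.24, adjusted p = 0.0006) and Krt8 by 0.72 (0.27, adjusted p = 0.052). Krt8 was called without a filter on low counts (0.000523), by DESeq2 (0.0245), by limma on log2(TPM + 1) (0.00391), from only the 6 libraries (0.0112) and without replicate 3 labelled shSox9 (0.0393). After subtraction of the 4T1 share Sox9 was not called (1.11, SE 0.62, edgeR adjusted p = 0.205). edgeR called 7719 genes, 3833 higher and 3886 lower, and of these 1478 and 2372 changed at least 2-fold. limma on log2(TPM + 1) called 8789 higher and 1962 lower, with a shift of all genes by 0.45. All 21 AT2 genes fell (median -2.25, camera adjusted p = 9.8e-28, and adjusted p = 0.088 with an estimated correlation), as did 16 of 17 AT1 genes (median -2.60, adjusted p = 0.026 with an estimated correlation) and 13 of 13 ciliated cell genes (median -6.44, adjusted p = 0.013 with an estimated correlation). Cell cycle genes rose in 23 of 24 cases (24 adjusted over the list alone, median 1.36, camera adjusted p = 9.8e-12, and adjusted p = 0.37 with an estimated correlation), but after subtraction of the 4T1 share the median was -0.50 (adjusted p = 0.160). Mesenchymal transition genes rose in 14 of 20 cases (median 1.48, adjusted p = 0.013 with an estimated correlation). Antigen presentation genes fell in 11 of 14 cases (median -0.69, camera adjusted p = 1.2e-05, and adjusted p = 0.41 with an estimated correlation).

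Against distal epithelium, rises were also called in these libraries for NF-kB and inflammatory genes (10 up and 4 down of 20, 11 and 4 adjusted over the list alone), TGF-beta, BMP and YAP response genes (9 and 2 of 16) and fibroblast genes (6 and 0 of 12), with medians of 0.66, 0.71 and 0.79 (camera adjusted p = 4.3e-05, 0.0042 and 3.5e-05, and adjusted p = 0.23, 0.27 and 0.27 with an estimated correlation). Falls were called for club cell (0 up and 12 down of 14), junction (2 and 14 of 18, 3 and 15 adjusted over the list alone), fatty acid synthesis (1 and 12 of 16) and lymphocyte genes (0 and 12 of 13), with medians of -3.79, -1.71, -0.90 and -1.33 (camera adjusted p = 1.9e-07, 2.2e-06, 9.3e-05 and 0.003, and adjusted p = 0.16, 0.41, 0.27 and 0.47 with an estimated correlation). The calls of immediate early genes (8 up and 2 down of 16, camera adjusted p = 0.027, and adjusted p = 0.65 with an estimated correlation) and cholesterol synthesis genes (0 and 10 of 18, 0.034, and adjusted p = 0.65 with an estimated correlation) were lost without replicate 3 labelled shSox9 (0.065 for both) or distal replicate 1 (0.057 and 0.120), and the first also without distal replicate 3 (0.090). Macrophage genes were not called (0 rose and 1 fell of 14, camera adjusted p = 0.92), nor were interferon-stimulated genes (2 rose and 13 fell of 22, adjusted p = 0.17), progenitor and stem-associated genes (13 and 8 of 24, 0.14) or mesothelial genes (0 and 4 of 6, 0.15). Camera called progenitor genes without replicate 1 (adjusted p = 0.041) or 3 (0.022) labelled shSox9, and mesothelial genes without replicate 2 (0.0088). The same fits called neither list with an estimated correlation (adjusted p = 0.45, 0.45 and 0.31).

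Changes from distal lung were compared between both niche groups. Of 9579 genes called in niche against distal epithelium, 6276 (65.5%, 95% Wilson interval 64.6% to 66.5%) were called in the same direction in the libraries labelled shSox9, and 124 in the opposite direction. Genes higher in both numbered 3130 and genes lower in both 3146, where independent lists would share 1092 and 1003. Across genes the log2 fold changes correlated at r = 0.847 with a covariance of 2.03. Simulated unchanged groups against the same distal libraries gave 0.523 and 0.0777, a covariance difference of 1.95. The 3 distal libraries cannot be parted so that each side keeps 2, so part of the excess in calls may come from shared controls. Medians depended on which group's calls chose the genes. Genes called higher in the niche had a median of 0.89 there and 0.55 in the libraries labelled shSox9, and genes called lower -1.41 and -0.96. For genes called in the libraries labelled shSox9, the medians were 0.81 in both groups for the higher ones, and -1.41 in the niche and -1.33 under the label for the lower ones.

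The series title concerns stem-like programs in both cell compartments, so the responses of 4T1 cells and of niche epithelium were compared over 13600 genes tested in both. Genes higher in vivo and higher in the niche numbered 1201, against 1206 for independent lists (Fisher's exact test across genes, Benjamini-Hochberg adjusted p over 4 tests = 0.853). Genes lower in both numbered 556 against 685 (adjusted p = 2.3e-10), and genes higher in vivo and lower in the niche 859 against 766 (adjusted p = 1.6e-05). Genes lower in vivo and higher in the niche numbered 1495 against 1078, an odds ratio of 2.06 (95% interval 1.90 to 2.24, adjusted p = 1.2e-67). Genes are not independent replicates in these tests. After subtraction of the 4T1 share the first of these became 1116 against 1023 (adjusted p = 8.5e-05) over 13389 genes, and the last 1130 against 925 (odds ratio 1.48, 95% interval 1.36 to 1.61, adjusted p = 7.9e-19). Of the progenitor list, Sox9, Etv4 (a 4T1 panel gene), Ly6a, Cd44, Itgb4 and Lgr6 were called higher in both compartments. Their number was not tested against chance. Ly6a changed by 7.07 and 0.61 (niche edgeR adjusted p = 0.026). After subtraction of the niche's estimated 4T1 RNA (11.7% to 20%), Sox9 (0 counts left) and Lgr6 were no longer called there.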

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

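Except for the splits of the libraries, the bound on leukocyte RNA and the test without the most abundant genes, the tests in this part were chosen after the results they measure had been seen. The 6 libraries of a comparison can be split in 10 ways into 3 and 3, too few for a share under 0.05. In each of the 4 comparisons 1 of the 10 splits, the real one, gave as many genes as were called, with 7151 genes for 4T1 cells in vivo against in vitro, 9579 for niche against distal epithelium, 3616 for niche libraries labelled shSox9 against niche and 7719 against distal epithelium. The highest of the other splits gave 0 genes by edgeR in each comparison. At an unadjusted p under 0.05 the real splits gave 8035, 10487, 5912 and 9070 genes and the highest others 316, 412, 1775 and 919, and no other tool was run on the splits. In the comparison treated as paired, 4 splits part all 3 pairs, and the others of these gave 0 genes.

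Antigen presentation genes were higher than distal in the niche (camera adjusted p = 0.033) and lower than distal in the libraries labelled shSox9 (adjusted p = 1.2e-05). With an estimated correlation these adjusted p values were 0.65 and 0.41, and the first call was also lost without niche replicate 3 (0.067) or distal replicate 2 (0.065). Tested directly, the median difference between both niche groups was -1.36 (camera adjusted p = 6.1e-30, and adjusted p = 0.14 with an estimated correlation), and the macrophage gene C1qa moved with it, from 437 ± 70.9 to 59.6 ± 49.4 CPM. This item was singled out by a rule narrowed after the list results had been seen, to lists called in opposite directions against distal lung.

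Sox9 and 11 other progenitor genes were higher in niche than in distal epithelium, in libraries with an estimated 17.2% ± 4.79 of 4T1 RNA. Set against the 4T1 in vivo level, Sox9 above distal came to 0.769 ± 0.0884 (SD, n = 3) of the panel's share, so 4T1 RNA may account for the whole rise. Taking off the distal level and this share left -13.1 ± 3.29 CPM, and Sox9 transcription in the epithelial cells cannot be told apart from its absence, because the spread of the panel leaves room for a low level. 4T1 RNA as the whole cause was argued against for 4 of the 9 genes outside the panel (Sox4, Ly6a, Cd44 and Aldh1a3), which at their level in 4T1 cells in vivo would need a larger share than the 95th percentile of the panel genes in each of the 3 niche libraries (Cd44 57.9%, 48.7% and 48.7%, against 36.4%, 40.6% and 22.4%), as 1 of the 56 panel genes also would; for Ly6a and Aldh1a3 that level (168 and 0.355 CPM) lay below the distal level (233 and 2.19 CPM). It stays open for the other genes: 2 (Myc and Itgb4) were still called higher after subtraction but needed a share within that spread, 2 (Etv4 and Hmga2) belong to the panel, so that the subtraction tests neither, and for 3 the call ended because subtraction took their counts to the distal level or below (Lgr6 at 1.60, SE 0.41, before and -0.94, 0.72, after, Itga6 at 0.97, 0.22, and -0.45, 0.32, and Tm4sf1 at 0.94, 0.16, and -1.56, 0.16, then called lower).

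Interferon-stimulated and antigen presentation genes were higher in 4T1 cells from lung than from culture (adjusted p = 0.22 and 0.15 with an estimated correlation). RNA of the lung epithelial sort would need to make up a median of 45.7% and 45.4% of the libraries to bring these levels, against a measured 1.85% to 4.26%, or 1.71% to 3.79% without the 3 panel genes of these lists, which argues against it as the cause. For leukocyte RNA a bound was set beforehand at 0.61, a fixed part of the macrophage genes' change of 2.43 between in vivo replicates 3 and 1: interferon-stimulated genes (0.77) and class II genes (1.44) lay above it and class I and processing genes (0.50, upper quartile 0.59) below it by less than their quartile range. The bound is not used for a verdict, because a single library, replicate 3, already known to hold the most Lyz2 and Xist, decides all 3 values, so leukocyte RNA stays open. Dissociation and sorting cannot be told apart from growth in the lung either, because immediate early genes rose in the same libraries (median 3.60) and the labels describe separate handling, while a response of the tumour cells to the lung stays open as untested.

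AT2 genes were lower in niche than in distal epithelium, with a median of -3.88. A lower share of epithelial cells with all other cell types rising alike was argued against by the markers, which moved apart by 4.25, from macrophage genes at 3.27 to lymphocyte genes at -0.98, more than the quartile range of either list; a rise of macrophage RNA alone stays open. The AT2 median was -3.48 (quartile range 1.05) after the 4T1 share was subtracted and -3.72 (1.41) without the 22 most abundant genes, which argues against 4T1 RNA and a few abundant genes as whole causes. After subtraction AT2 genes lay 1.40 below epithelial junction genes (median -2.08, quartile range 1.64), so lower expression of AT2 genes in niche epithelial cells may contribute. It cannot be told apart from RNA of other cells in the sort, whose own profiles were not measured, or from another mix of epithelial cell types.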

How the results depend on the processing

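Subtracting the 4T1 share, the added panels, the block with 6 libraries and the fit without genes a 5% lung RNA share could account for were chosen after the data were seen. Counts of called genes stayed within 1.5 times under every setting run except for niche libraries labelled shSox9 against niche, 2238 without niche replicate 1. With each replicate left out, counts ran from 6034 to 7378 (4T1 in vivo against in vitro), 8502 to 9044 (niche against distal), 2238 to 4224 (labelled shSox9 against niche) and 6581 to 7715 (labelled shSox9 against distal). The log2 fold change of Sox9 ran from 0.51 to 0.75, 2.91 to 3.31, -0.05 to 0.51 and 3.03 to 3.61, and the number of lists called from 19 to 19, 14 to 16, 11 to 17 and 13 to 16. With an estimated correlation camera called 1, 4, 0 and 3 lists, in place of 19, 16, 13 and 15. DESeq2 called 7412, 9877, 4150 and 8020 genes.

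After subtraction edgeR called 8246, 4191 and 6131 genes in the epithelial comparisons, of which 3845, 1604 and 2486 were called higher and 3527, 1866 and 2897 lower both times. It left 0 Sox9 counts in the niche against 260 in distal, so no fold could be given, as for 9 further gene values dropped after being seen. Sox9 under the label against distal became 1.11 (SE 0.62, edgeR adjusted p = 0.205), and the niche response shared under the label 55.6%. Hmga2 (-1.87, adjusted p = 0.111), Nrarp (-1.51, adjusted p = 0.263) and the cell cycle list against distal under the label (camera adjusted p = 0.160, 8 of 24 genes called lower and 5 higher) changed direction. Too much may thus have been subtracted. The planned 4T1 panel at 50 and 0.5 CPM held 3 genes and gave a niche mean of 35.6% in place of 20.7% from 2 genes, and the cause was not tested; the added panel with a ratio of 50 gave 15.6%. Under the label these panels gave 6.09% and 6.99%, below the 15.1% that was subtracted there.

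Over all alternatives, called genes named by the rule kept the call in 4629 cases, lost it in 235 and turned in 2. Called lists did so in 484, 77 and 1. Those not called stayed so in 101 cases for genes and 491 for lists, and gained a call in 19 and 23. The rule omits Tm4sf1, Lgr6 and Itga6, which turned. With the replicate block edgeR called 7487, 9500, 3638 and 7692 genes, and 3987 with 6 libraries. In the paired comparison the block changed the calls of ciliated and fibroblast genes, and with 6 libraries of fibroblast and oxidative phosphorylation genes, and of no other list. Among the others it called progenitor genes against distal under the label (adjusted p = 0.049, and adjusted p = 0.48 with an estimated correlation) and no longer oxidative phosphorylation genes in niche against distal (0.051). These comparisons share only a number, with correlations of 0.125, 0.0129 and 0.134 (4T1 in vivo and in vitro), 0.111, 0.0551 and -0.0423 (distal and niche) and -0.0949, 0.151 and -0.104 (distal and labelled shSox9). Depth limits genes near 0.0986 to 0.189 CPM, the floor of 3 counts.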

Other observations

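The tests of the hairpin and the subtraction of the 4T1 share in this part were chosen after the result was seen. Of 12 Wnt targets 4 rose and 6 fell between distal and niche epithelium, and the list was not called (camera adjusted p = 0.16). Sox9 was among those that rose, with the transcription factors Lef1 at 1.46 (SE 0.26) and Tcf7 at 1.27 (0.22) and with Apcdd1 at 1.08 (0.40, edgeR adjusted p = 0.038, and 0.72 after subtraction of the 4T1 share). Of those that fell, the transcription factor Sp5 changed by -4.50 (SE 0.39), the receptor ligase Rnf43 by -3.59 (0.39) and Nkd1 by -3.09 (0.12), from 122.5 ± 13.0 to 14.3 ± 1.35 CPM (SD, n = 3). In the libraries labelled shSox9 Nkd1 stood at 33.4 ± 2.65 CPM. Of the Notch pathway, the target Heyl changed by 1.89 (0.18) and the ligand Jag1 by -1.06 (0.12). Of p53 targets, the pro-apoptotic gene Bax changed by 0.92 (0.09) and Trp53inp1 by -2.29 (0.21). In 4T1 cells in vivo Trp53inp1 changed by 2.17 (0.34), the receptor Notch1 by 1.12 (0.15), its ligand Dll4 by -1.33 (0.20), the asparagine synthetase Asns by -1.25 (0.11) and the chaperone Dnajb9 by 1.23 (0.12). The edgeR adjusted p of each gene but Apcdd1 was at most 0.00068.

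Since Sox9 was not lower under the label, 2 hypotheses on the hairpin were tested. If it had halved Sox9 RNA in the 4T1 cells, the ratio of Sox9 to the 4T1 panel would be lower to that extent, but it was 0.769 ± 0.0884 in the niche and 1.08 ± 0.140 under the label (SD, n = 3), a difference of 0.306 (exact permutation test, two-sided, p = 0.1, and exact sign flips within the 3 pairs, p = 0.25, each the smallest possible). With the planned panel of 2 genes the ratio was 0.652 ± 0.0519 and 2.70 ± 1.39, so that both panels argue against this. If the hairpin acted in the lung epithelial cells, Sox9 left after the distal level and the 4T1 share would be lower. It was -13.1 ± 3.29 CPM in the niche and 5.55 ± 7.93 under the label. They differed by 18.6 CPM (exact permutation p = 0.1, sign flips p = 0.25). With nothing left to lower in the niche, this hypothesis stays open. A smaller effect on RNA, an effect on protein alone and a wrong label were not tested.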
